A study of Mus musculus with 7 samples.

How the data were processed

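Polyadenylated RNA of the abdominal aorta of male Ang II-exposed mice was sequenced from strand-marking libraries (TruSeq Stranded mRNA), per the labels' protocols. Reads were handled with Trimmomatic, HISAT2, HTSeq, Cufflinks and DESeq against GRCm38.p6, per the submitters' processing notes, which give no versions and no roles. The gene annotation, the alignment filters and whether counting used strand are not given in the sources used here, so antisense and overlapping genes, and close paralogs, are uncertain. The tables used cover the whole series: the deposited gene counts, whole numbers that were not normalized, and the deposited FPKM values, which the authors scaled for gene length and depth. Columns were matched to samples by the genotype and number in their names.

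The count table had 21878 genes, 4054 of them with no count in any library, and 27 symbols had been turned into dates and were restored through their gene identifiers. edgeR's filterByExpr (minimum count 10) left 14609 genes, and 14577 of these had a RefSeq identifier on GRCm38.p6, from which coordinates were taken. Library totals were 19295287 to 21727192 counts, and a difference between groups was not shown (20.5 ± 1.08 M, SD, n = 3, against 20.7 ± 0.82 M, SD, n = 4; exact two-sided permutation p = 0.857). The lowest chi-square per gene between any 2 libraries was 35.2, so no library repeated another. Counts were normalised by TMM and tested with edgeR's quasi-likelihood test on the 3 libraries labelled ApoE-/- and the 4 labelled double knockout, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the absolute log2 fold change over the square root of F. Levels are CPM on TMM-scaled library sizes, and list levels are means of log2 CPM (prior count 2). Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

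Gene lists (43) for aortic and immune cell types, vascular and immune processes, metabolism, stress, blood, bordering tissues and the clock were fixed before the data were examined, as were the tests, the rule for named genes and most of the alternative settings. Lists with at least 5 measured members (42) were tested with limma's camera (preset correlation 0.01), with the correlation estimated per list and with fry as alternatives. A list's p-values were also adjusted over the list alone. Named genes were Nr4a1, Apoe, Olr1, Nr4a2 and Nr4a3; up to 12 genes per direction with adjusted p under 0.05, an absolute log2 fold change of at least 1, no overlap of CPM and a mean log2 CPM of at least 1; and, of each list, up to 3 members with adjusted p under 0.05, or else the 1 with the smallest p. Other members that the text names (Adipoq, Pnpla2, Ucp1, Dpt, Birc5, Cx3cr1, Arntl, Npas2, Dbp, Per2, Acta2, Hspa5, Hsp90b1, Ddit3) were chosen after their values were seen.

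The test was tried on simulated counts with the real means, library sizes and dispersions and 200 changed genes. It recovered 0% of genes changed 1.5-fold, 34.0% of those changed 2-fold and 87.5% of those changed 4-fold, with 0, 7 and 9 false calls (at 2-fold a larger share of the calls than the threshold of 0.05), among 14461 to 14483 genes tested. The changed genes were drawn from those with a log2 CPM above 1. Each gene was simulated independently, so these figures do not cover shifts that many genes of a library share. Alternatives planned before the data were examined were RLE size factors, DESeq2, limma voom with quality weights, no low-count filter and a minimum count of 50, the replicate number as a block, each library left out, and limma on log2 FPKM with pseudocounts of 1 and 0.1 and a minimum mean of 1 or none. Counting called lists with DESeq2-normalised counts, a pseudocount of 0.1 or unfiltered FPKM was chosen after seeing the data, and other alternatives chosen then left out ApoE 3 and DKO 1 together, took the white adipocyte level as a covariate, or removed a trend in gene length or GC content of GENCODE M21 transcripts from each library (lowess span 0.3; 96.9% of tested genes had both).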

Results

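RNA was sequenced from the abdominal aorta of male C57BL/6 mice aged 8 weeks that had been exposed to angiotensin II (Ang II), a pressor peptide that induces aortic aneurysm in hyperlipidaemic mice, for up to 28 days. Of the 7 libraries, 3 were labelled ApoE-/- (ApoE 1 to ApoE 3) and 4 were labelled ApoE-/-Nur77-/-, the double knockout (DKO 1 to DKO 4). ApoE is the apolipoprotein whose loss raises plasma cholesterol, and Nur77 is the nuclear receptor encoded by Nr4a1. The comparison between the groups asks what loss of Nur77 changes in the Ang II-exposed aorta on the ApoE-/- background. Gene counts summed to between 19295287 and 21727192 per library, and 14609 genes were tested. A count of 0 allowed a level of up to 0.138 to 0.155 CPM (counts scaled to a common library size), a floor that covers counting error only. The labels do not say that each library came from a separate mouse, so p-values of the tests of single genes and of library levels measure the spread between these libraries. The camera tests at a preset correlation of 0.01 treat the genes of a list as nearly independent, so their p-values do not measure that spread.

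The targeted genes did not follow the labels. Nr4a1 (chromosome 15, 101253902 to 101274795, GRCm38.p6) was read at 120.0 ± 68.5 CPM (SD, n = 3) in the libraries labelled ApoE-/- and at 71.5 ± 23.4 CPM (SD, n = 4) in those labelled double knockout. The per-library values were 193, 56.4 and 111 CPM against 46.2, 57.0, 90.1 and 92.7 CPM. The log2 fold change was -0.75 (SE 0.42, edgeR adjusted p = 0.360), so a difference was not shown, and it was -0.23 without ApoE 1. Apoe (chromosome 7, 19696244 to 19701310), which the labels give as knocked out in both groups, was read at 222 ± 34.4 CPM (SD, n = 3) in the libraries labelled ApoE-/- and at 28.7 ± 7.52 CPM (SD, n = 4) in those labelled double knockout. That is 7.73-fold lower in the latter (log2 fold change -2.95, SE 0.23, edgeR adjusted p = 0.0227). The sources used here do not say which part of either gene is deleted, and gene counts can hold reads from any part of a transcript that an altered allele still makes. Every direction given here is therefore that of the libraries labelled double knockout against the libraries labelled ApoE-/-. The Nur77 relatives Nr4a2 (log2 fold change -0.38, SE 0.22, adjusted p = 0.379) and Nr4a3 (log2 fold change -0.79, SE 0.26, adjusted p = 0.178) did not pass the threshold.

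**Figure D1:**
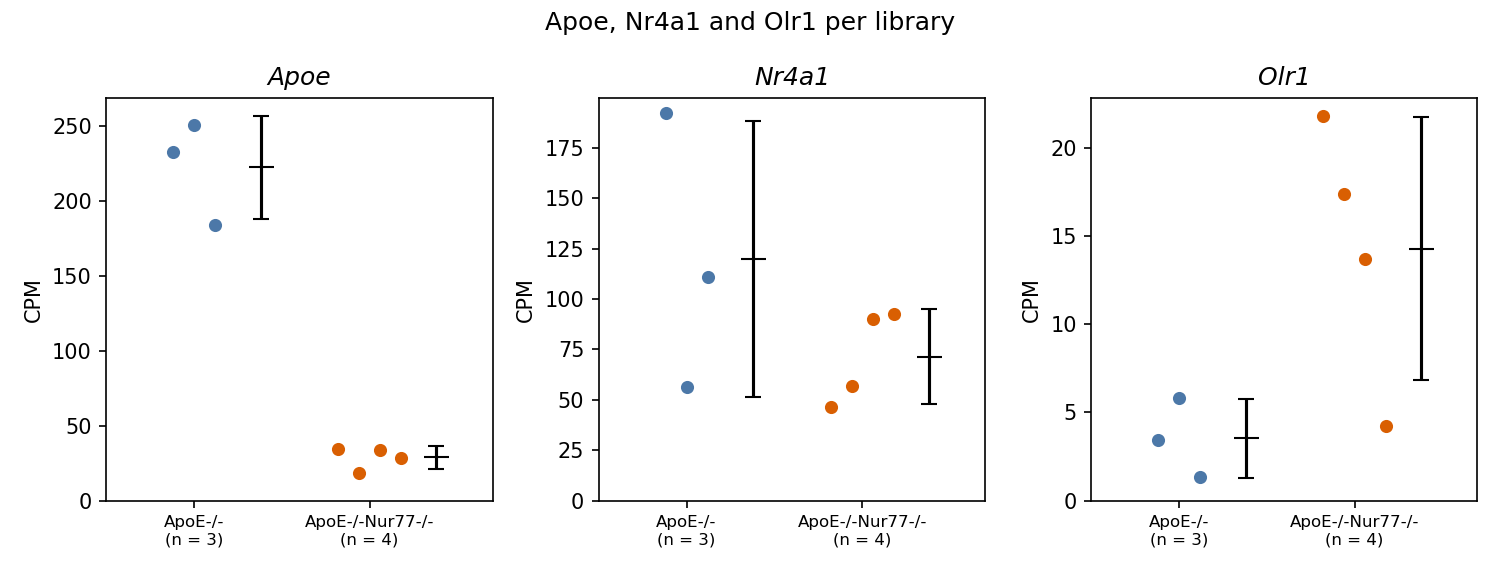
CPM of Apoe, Nr4a1 and Olr1 in each library (points), with the mean and SD of each group (bar and whiskers), for the 3 libraries labelled ApoE-/- and the 4 labelled ApoE-/-Nur77-/-. Apoe separated the groups (222 against 28.7 CPM on average), Nr4a1 overlapped between them, and DKO 4 (4.24 CPM) lay among the libraries labelled ApoE-/- for Olr1.

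Across all genes, 4 were lower and 0 were higher in the libraries labelled double knockout at adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). Besides Apoe, these were Slc1a5, a glutamine transporter (783 ± 200 CPM, SD, n = 3, against 150.1 ± 21.6 CPM, SD, n = 4; log2 fold change -2.38, SE 0.20, adjusted p = 0.0227), Lpin1, a phosphatidate phosphatase of triglyceride synthesis (126 ± 11.7 against 56.3 ± 4.33 CPM; log2 fold change -1.16, SE 0.10, adjusted p = 0.0227), and Slc7a10, a neutral amino acid transporter of adipocytes (35.4 ± 3.21 against 14.5 ± 1.699 CPM; log2 fold change -1.29, SE 0.12, adjusted p = 0.0415). Slc1a5 (chromosome 7, 16781334 to 16798274) and Slc7a10 (chromosome 7, 35186095 to 35201116) lie on the chromosome of Apoe, and Lpin1 lies on chromosome 12 (16535669 to 16653903). At an unadjusted p under 0.05 there were 1168 genes higher and 1724 lower, against 730 of both kinds by chance on average. Regrouping the libraries could give more: DKO 1, DKO 2 and DKO 3 against the rest gave 4744, and ApoE 1, ApoE 3 and DKO 4 against the rest gave 4608. The values of the groups did not overlap for 16.3% of genes, against 5.71% by chance on average. How far other groupings stray from that share was not counted. The counts depended on the tool: DESeq2's Wald test called 453 higher and 679 lower, and limma voom with sample quality weights called 902 higher and 1467 lower. Leaving out ApoE 1, ApoE 3, DKO 3 or DKO 4 left 0 genes lower, leaving out ApoE 2 or DKO 2 left 1, and leaving out DKO 1 gave 2 lower and 4 higher.

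Adipocyte genes and genes of mitochondrial energy production were lower as groups. Of the 17 measured white adipocyte genes, 17 had negative fold changes (median log2 fold change -1.05), 0 passed adjusted over all genes and 16 passed adjusted over the list alone. They included Acsl1, which activates fatty acids (580 ± 78.9 CPM, SD, n = 3, against 300.5 ± 41.4 CPM, SD, n = 4; log2 fold change -0.95, SE 0.15), the adipokine gene Adipoq (600.2 against 327 CPM) and the lipase gene Pnpla2 (1079 against 449 CPM). The mean log2 CPM of the list was 8.91 ± 0.26 (SD, n = 3) and 7.83 ± 0.21 (SD, n = 4), without overlap (exact two-sided permutation p = 0.0571, the smallest that 35 splits allow). Of the 12 brown adipocyte genes, 12 were negative (median -1.44) and 10 passed adjusted over the list alone. Ppargc1a, a coactivator of mitochondrial genes, was at 11.8 ± 3.11 against 4.30 ± 0.72 CPM (log2 fold change -1.45, SE 0.24), and the uncoupling protein gene Ucp1 was at 502 ± 279 against 158 ± 84.4 CPM. Ucp1 overlapped between groups, at 256 CPM in DKO 1 and 242 CPM in ApoE 2. All 20 oxidative phosphorylation genes were negative (median -0.77) and 20 passed adjusted over the list alone, Cox4i1 among them (576 ± 170 against 320.1 ± 45.0 CPM). Of the 17 fatty acid oxidation genes, 16 passed adjusted over the list alone (median -0.88), Cpt2 with a log2 fold change of -0.98 (SE 0.24). Cpt1b was on both the brown adipocyte and the fatty acid oxidation lists. With camera at a preset correlation the adjusted p was 3.20e-12 for white adipocyte, 1.12e-09 for oxidative phosphorylation, 4.21e-08 for fatty acid oxidation and 4.98e-07 for brown adipocyte genes. The correlation estimated from the data was 0.46 for white adipocyte, 0.95 for oxidative phosphorylation, 0.75 for fatty acid oxidation and 0.69 for brown adipocyte genes. With an estimated correlation the camera adjusted p was 0.728 for each of the 4. Without ApoE 3 the medians were nearer 0, at -0.49 for oxidative phosphorylation, -0.58 for fatty acid oxidation and -0.96 for brown adipocyte genes, and each list was still called. ApoE 3 had the highest oxidative phosphorylation level (8.03 log2 CPM). A list of atrial cardiomyocyte genes, chosen after the data were seen, was also highest in ApoE 3 and ApoE 2. Its levels there were 6.92 and 5.06 log2 CPM, against -0.35 to 1.47 in the other libraries.

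Adventitial fibroblast genes were lower beside them. Of 16 measured, 12 were negative (median log2 fold change -0.47) and 8 passed adjusted over the list alone, all lower. Pi16, a marker of adventitial progenitor-like fibroblasts, was at 911 ± 302 CPM (SD, n = 3) against 333 ± 72.4 CPM (SD, n = 4; log2 fold change -1.45, SE 0.25, adjusted p = 0.115), and Dpt, a matrix protein gene, was at 627 against 439 CPM. The camera adjusted p was 2.82e-04 (adjusted p = 0.728 with an estimated correlation), and the level of the list did not overlap between groups (8.83 ± 0.09 against 8.37 ± 0.09 log2 CPM). Glycolysis genes had a median of -0.32 with 15 of 17 negative, 0 passed adjusted over the list alone, and Hk2, the hexokinase of muscle and fat, had a log2 fold change of -0.80 (SE 0.21). Their camera adjusted p was 0.0335 (adjusted p = 0.728 with an estimated correlation), and 0.106 without ApoE 3 (median -0.16), 0.112 without DKO 3 and 0.123 without DKO 4.

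Proliferation and lymphocyte lists were called higher by camera, with levels that overlapped between groups. In the cell cycle list DKO 4 (3.24 log2 CPM) lay below ApoE 2 (3.30), and in the B cell list ApoE 2 (3.20) lay above 3 of the 4 libraries labelled double knockout. Of 19 measured cell cycle genes, 19 were positive (median log2 fold change 0.59) and 8 passed adjusted over the list alone. Mki67, a marker of cycling cells, was at 23.7 ± 6.04 CPM (SD, n = 3) against 53.9 ± 16.5 CPM (SD, n = 4; log2 fold change 1.19, SE 0.29, adjusted p = 0.153), and Birc5 was at 3.93 against 7.58 CPM. The camera adjusted p was 4.21e-08 (adjusted p = 0.728 with an estimated correlation). T and NK cell genes had a median of 0.72 with 17 of 18 positive, 0 passing adjusted over the list alone, and a camera adjusted p of 3.53e-04 (adjusted p = 0.728 with an estimated correlation). Their median was 0.41 without DKO 3. The member with the smallest p was Cd5 (1.84 ± 0.70 against 3.41 ± 0.77 CPM; log2 fold change 0.88, SE 0.36). B cell (median 0.65, 11 of 11 positive), plasma cell (median 1.30, 6 of 6 positive) and tertiary lymphoid organ genes (median 0.42, 9 of 9 positive) had camera adjusted p of 0.0260, 0.0310 and 0.0412, and of 0.728 each with an estimated correlation. Of the 15 genes on the plasma cell list only 7 were in the count table and 6 were measured, so its median rests on a small part of the list. No member of these lists passed adjusted over the list alone. Prdm1, a plasma cell transcription factor, had a log2 fold change of 1.23 (SE 0.41, adjusted p = 0.183), Ccl21a, a lymphoid chemokine, 0.82 (SE 0.23, adjusted p = 0.159), and Fcrla of B cells 1.05 (SE 0.72, adjusted p = 0.442). The B cell median was 0.24 without ApoE 1, 2.63 without ApoE 2, 0.14 without ApoE 3 and 0.019 without DKO 3. The plasma cell median was 2.55 without ApoE 2. The B cell call was lost without ApoE 1 (adjusted p = 0.0809), ApoE 3 (0.192), DKO 1 (0.0655) or DKO 3 (0.0958). The plasma cell call was lost without ApoE 3 (0.0891), DKO 1 (0.0622) or DKO 3 (0.0675). The tertiary lymphoid organ call was lost without ApoE 1 (0.0809), ApoE 3 (0.186), DKO 1 (0.0622), DKO 3 (0.115) or DKO 4 (0.0715). Its median was -0.07 without ApoE 3, 1.23 without ApoE 2, 0.72 without DKO 2, 0.11 without DKO 3 and 0.69 without DKO 4.

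The macrophage, chemokine and collagen lists were called higher by camera, with no member that passed higher adjusted over the list alone. Macrophage and monocyte genes had a median log2 fold change of 0.33 with 16 of 20 positive (camera adjusted p = 0.0268; adjusted p = 0.728 with an estimated correlation). The only member that passed adjusted over the list alone went the other way: Cd163, a haemoglobin scavenger receptor of resident macrophages, was at 57.1 ± 23.2 CPM (SD, n = 3) against 20.5 ± 5.76 CPM (SD, n = 4; log2 fold change -1.48, SE 0.31, adjusted p = 0.133 over all genes), while the chemokine receptor gene Cx3cr1 was at 22.3 ± 4.75 against 47.1 ± 14.6 CPM. The macrophage call was lost without ApoE 1 (adjusted p = 0.0692), ApoE 3 (0.118), DKO 1 (0.0965) or DKO 3 (0.112). The median was 0.51 without ApoE 2, 0.20 without ApoE 3 and 0.19 without DKO 3. Chemokine and cytokine genes had a median of 0.41 with 20 of 23 positive, 0 passing adjusted over the list alone, and Ccl7 at a log2 fold change of 0.70 (SE 0.21). Their camera adjusted p was 0.00812 (adjusted p = 0.728 with an estimated correlation), and 0.116 without ApoE 3 (median 0.26) and 0.0655 without DKO 1. The median was 0.25 without DKO 3. Collagen matrix genes had a median of 0.28 with 18 of 22 positive, 0 passing adjusted over the list alone, and Plod2, a collagen lysyl hydroxylase, at 0.48 (SE 0.15). Their camera adjusted p was 0.0317 (adjusted p = 0.728 with an estimated correlation), and 0.183 without ApoE 2 and 0.146 without DKO 2 (median 0.16).

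Olr1 encodes LOX-1, a receptor for oxidised low-density lipoprotein, and was chosen for report before the data were examined. It was at 3.52 ± 2.27 CPM (SD, n = 3) in the libraries labelled ApoE-/- and at 14.3 ± 7.48 CPM (SD, n = 4) in those labelled double knockout (chromosome 6, 129479150 to 129507350). The log2 fold change of 2.01 (SE 0.66) did not pass edgeR's test (adjusted p = 0.176). It passed with DESeq2's Wald test (adjusted p = 0.0172) and with limma voom (adjusted p = 0.0441). These were the only 2 calls in 20 alternatives, whose adjusted p reached 0.690. The voom fit gave a quality weight of 0.41 to DKO 4, the library labelled double knockout with the lowest Olr1 level (4.24 CPM). Adjusted over the list alone, no scavenger receptor and cholesterol handling gene passed, and the list (median 0.51, 11 of 14 positive) had a camera adjusted p of 0.146 (0.0172 without DKO 4; median 0.32 without DKO 3). Its member with the smallest p was Scarb1, the receptor for high-density lipoprotein (log2 fold change -0.35, SE 0.10, adjusted p = 0.160).

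Circadian clock genes of opposite phase differed in opposite directions. Of 15 measured, 3 were higher and 9 lower adjusted over the list alone. Arntl, the core activator also called Bmal1, was at 3.84 ± 0.52 CPM (SD, n = 3) against 31.1 ± 16.4 CPM (SD, n = 4; log2 fold change 3.02, SE 0.60, adjusted p = 0.129), Npas2 at 2.04 ± 0.36 against 30.2 ± 18.7 CPM (log2 fold change 3.88, SE 0.89, adjusted p = 0.146) and Clock at 47.9 ± 3.75 against 73.7 ± 8.45 CPM (log2 fold change 0.62, SE 0.11, adjusted p = 0.1202). The output gene Dbp was at 223 ± 84.5 against 58.1 ± 57.4 CPM and the repressor gene Per2 at 137 ± 15.2 against 48.1 ± 26.4 CPM. DKO 1 lay near the libraries labelled ApoE-/- in both sets of genes, and without it Arntl and Npas2 were called higher over all genes (adjusted p = 0.00134 for both). The list as a whole had a median of -0.87, and its camera adjusted p was 0.0466 (adjusted p = 0.728 with an estimated correlation). That call was lost without ApoE 1 (0.0809), ApoE 3 (0.0708), DKO 2 (0.0549), DKO 3 (0.0608) or DKO 4 (0.1005).

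**Figure D2:**
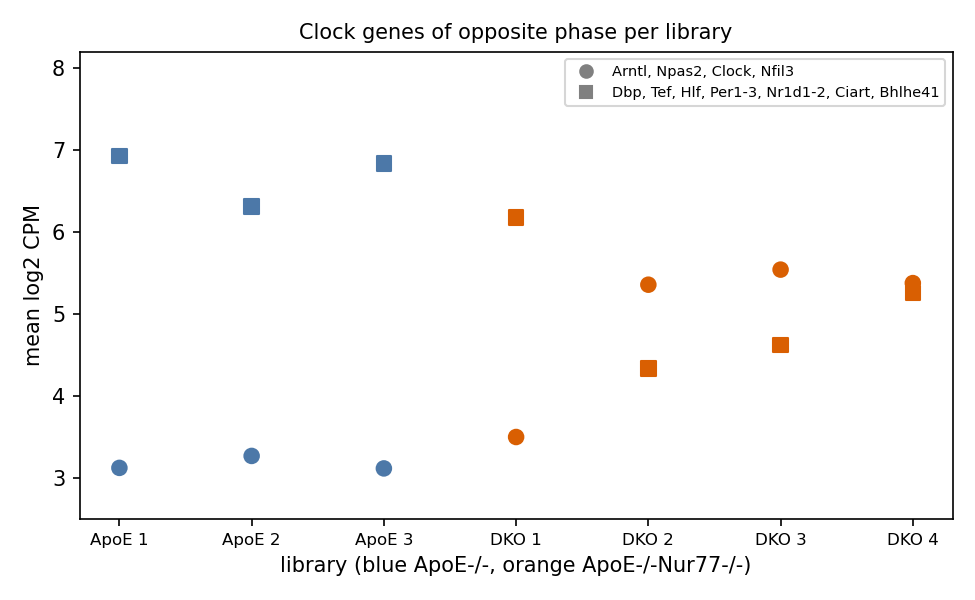
Mean log2 CPM of 4 clock genes of the Arntl phase (circles) and 10 of the Dbp phase (squares) in each library, in blue for libraries labelled ApoE-/- and in orange for those labelled ApoE-/-Nur77-/-. The circles of DKO 2, DKO 3 and DKO 4 lay at 5.35, 5.54 and 5.37, and that of DKO 1 at 3.50, near the 3.11 to 3.26 of the libraries labelled ApoE-/-.

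In all, camera called 8 lists higher and 7 lower of 42 tested, and 27 were not called (adjusted p 0.0601 to 0.915). The levels of all 8 lists called higher overlapped between groups (exact two-sided permutation p 0.114 to 0.571), as did glycolysis among the 7 called lower. With an estimated correlation 0 were called, and fry, which tests each list on its own, called 0 higher and 2 lower, adventitial fibroblast (adjusted p = 0.0319) and white adipocyte (adjusted p = 0.0392). Among lists of the vessel wall that were not called, elastic fibre and assembly genes had a median of 0.14 (adjusted p = 0.102) with levels that did not overlap between groups. The member with the smallest p was Lox, the enzyme that crosslinks elastin and collagen (376 ± 26.6 CPM, SD, n = 3, against 691 ± 185 CPM, SD, n = 4; log2 fold change 0.88, SE 0.21, adjusted p = 0.152). Contractile smooth muscle genes had a median of -0.24 (adjusted p = 0.106) with Acta2 at 7805 ± 1557 against 6581 ± 3702 CPM; Pln, the member with the smallest p (log2 fold change -2.48, SE 0.64), is also a cardiac gene. Matrix-degrading proteases had a median of 0.24 (adjusted p = 0.0601), Plau among them at 1.10 (SE 0.28). Basement membrane genes had a median of 0.17 (adjusted p = 0.145; Lama2 -0.82, SE 0.22), endothelial genes -0.15 (adjusted p = 0.273; Eng -0.26, SE 0.11), protease inhibitors -0.23 (adjusted p = 0.279; Timp4 -1.19, SE 0.36) and TGF-beta signalling 0.03 (adjusted p = 0.213). In the last list 1 gene passed adjusted over the list alone, the SMAD corepressor gene Skil (log2 fold change 0.43, SE 0.09). The chondro-osteogenic median was 0.51 (adjusted p = 0.891; Alpl -0.86, SE 0.22), the renin-angiotensin median -0.08 (adjusted p = 0.412; Ace -0.38, SE 0.18) and the NADPH oxidase median 0.26 (adjusted p = 0.151; Cybb 0.63, SE 0.33). The antioxidant response median was 0.04 (adjusted p = 0.915; Sod1 -0.73, SE 0.18), with fry pointing lower where the median, mean and camera pointed higher. Of 15 measured antioxidant response genes, 8 were positive and 7 negative, Sod1 among the latter. Leaving out 1 library gave calls for some of these lists. Contractile smooth muscle was called without DKO 4 (median -0.69, adjusted p = 2.14e-04), and its median was -0.013 without DKO 1. Endothelial genes were called without ApoE 2 (adjusted p = 0.0479). Elastic fibre genes were called without ApoE 3 (0.0346) or DKO 3 (0.0478), and their median was 0.26 without DKO 1 and 0.045 without DKO 2. The medians ranged from 0.05 to 0.26 for basement membrane, -0.21 to -0.04 for endothelial and -0.34 to -0.12 for protease inhibitor genes. They ranged from 0.14 to 0.46 for NADPH oxidase, 0.024 to 0.118 for TGF-beta signalling and 0.16 to 0.35 for matrix-degrading protease genes. Matrix-degrading proteases were called without ApoE 1 (0.0492), ApoE 2 (0.0442), DKO 2 (0.0282) or DKO 4 (0.0136).

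Among stress and immune lists that were not called, 5 unfolded protein response genes were higher and 2 lower adjusted over the list alone (median 0.24, camera adjusted p = 0.0669). The chaperone genes Hspa5 (log2 fold change 0.61, SE 0.12) and Hsp90b1 (0.47, SE 0.11) were among the former, and Herpud1 (-0.60, SE 0.10), which acts in endoplasmic reticulum-associated degradation, and Ddit3 (-0.56, SE 0.18) were the latter. Immediate early genes had a median of -0.03 (adjusted p = 0.783), with 1 higher and 1 lower adjusted over the list alone, and Fosl2 at 0.49 (SE 0.11). Interferon response genes had a median of -0.08 (adjusted p = 0.556), and Ifit3 (log2 fold change -0.66, SE 0.13) was the 1 member that passed adjusted over the list alone. Neutrophil genes had a median of 1.12 (adjusted p = 0.205; Lcn2 -0.65, SE 0.33), foamy macrophage genes 0.18 (adjusted p = 0.766; Lpl -0.44, SE 0.15), MHC class II genes 0.15 (adjusted p = 0.125; Ciita 0.52, SE 0.31), NF-kB target and adhesion genes 0.15 (adjusted p = 0.273; Sod2 -0.86, SE 0.25), inflammasome genes 0.24 (adjusted p = 0.125; Txnip -0.74, SE 0.23) and complement genes -0.10 (adjusted p = 0.493). Of 12 measured neutrophil genes 11 were positive, and Lcn2 was the exception. With 1 library left out, neutrophil genes were called without ApoE 2 (median 1.97, adjusted p = 0.0442), and their median was 0.10 without DKO 1. MHC class II genes were called without ApoE 2 (median 0.32, adjusted p = 0.0131) or DKO 2 (adjusted p = 0.0178). Interferon response genes were called without ApoE 1 (median -0.20, adjusted p = 0.0457). The medians ranged from 0.04 to 0.22 for NF-kB and 0.16 to 0.33 for inflammasome genes, and that of unfolded protein response genes was 0.135 without DKO 1. Inflammasome genes were called without DKO 2 (adjusted p = 0.0392) and unfolded protein response genes without ApoE 1 (0.0459) or DKO 3 (0.0478).

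Of 9 lists of blood and of tissues that border the aorta, the levels of 5 overlapped between groups. The exceptions were white adipocyte genes (8.62 to 9.10 against 7.64 to 8.13 log2 CPM), brown adipocyte genes (5.42 to 6.71 against 4.12 to 5.06), platelet genes (1.6997 to 1.84 log2 CPM in the libraries labelled ApoE-/- and 1.99 to 2.45 in those labelled double knockout) and the kidney list (1.80 to 1.88 against 0.89 to 1.62). Skeletal muscle genes had mean levels of 3.09 log2 CPM in ApoE 3 and 2.56 in DKO 1, against -0.09 to 1.62 in the other 5 libraries (median log2 fold change -0.16, adjusted p = 0.423; Myl1 -1.69, SE 0.48). Adrenal gland genes were at 4.30, 4.76 and 4.92 log2 CPM in ApoE 1, ApoE 2 and DKO 2 and at -0.33 in ApoE 3 (median -0.39, adjusted p = 0.739). Of the 13 on the list only 6 were measured. These were Mc2r (1.43 against 0.82 CPM, log2 fold change -0.79, SE 0.43), Star (4.59 against 3.42 CPM), Dbh, Th, Chga and Chgb. The list level therefore does not show that adrenal gland was present. The medians were -0.50 for Schwann cell and nerve genes (adjusted p = 0.102; S100b -0.51, SE 0.23), -1.13 for mesothelium (adjusted p = 0.0901; Krt7 -1.07, SE 0.42), 0.80 for red blood cells (adjusted p = 0.138; Alas2 1.31, SE 0.63) and 0.13 for platelets (adjusted p = 0.102), where Itgb3, an integrin subunit also made by vessel and myeloid cells, was the 1 gene that passed adjusted over the list alone (log2 fold change 1.14, SE 0.14, adjusted p = 0.0994 over all genes). With 1 library left out, mesothelium genes were called without ApoE 1 (median -1.39, adjusted p = 3.05e-04). Schwann cell and nerve genes were called without ApoE 3 (median -0.78, adjusted p = 0.00249) or DKO 2 (0.0192). Red blood cell genes were called without ApoE 3 (median 1.57, adjusted p = 0.0140) or DKO 4 (0.0295), and platelet genes without DKO 4 (median 0.67, adjusted p = 0.0447). The median was -0.71 for mesothelium without ApoE 3 and 0.37 for red blood cells without ApoE 2, and ranged from 0.17 to 0.67 for platelets. Of the kidney list only 2 genes were measured, too few for the set test, and Aqp2 had a log2 fold change of -1.42 (SE 0.39).

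**Figure D3:**
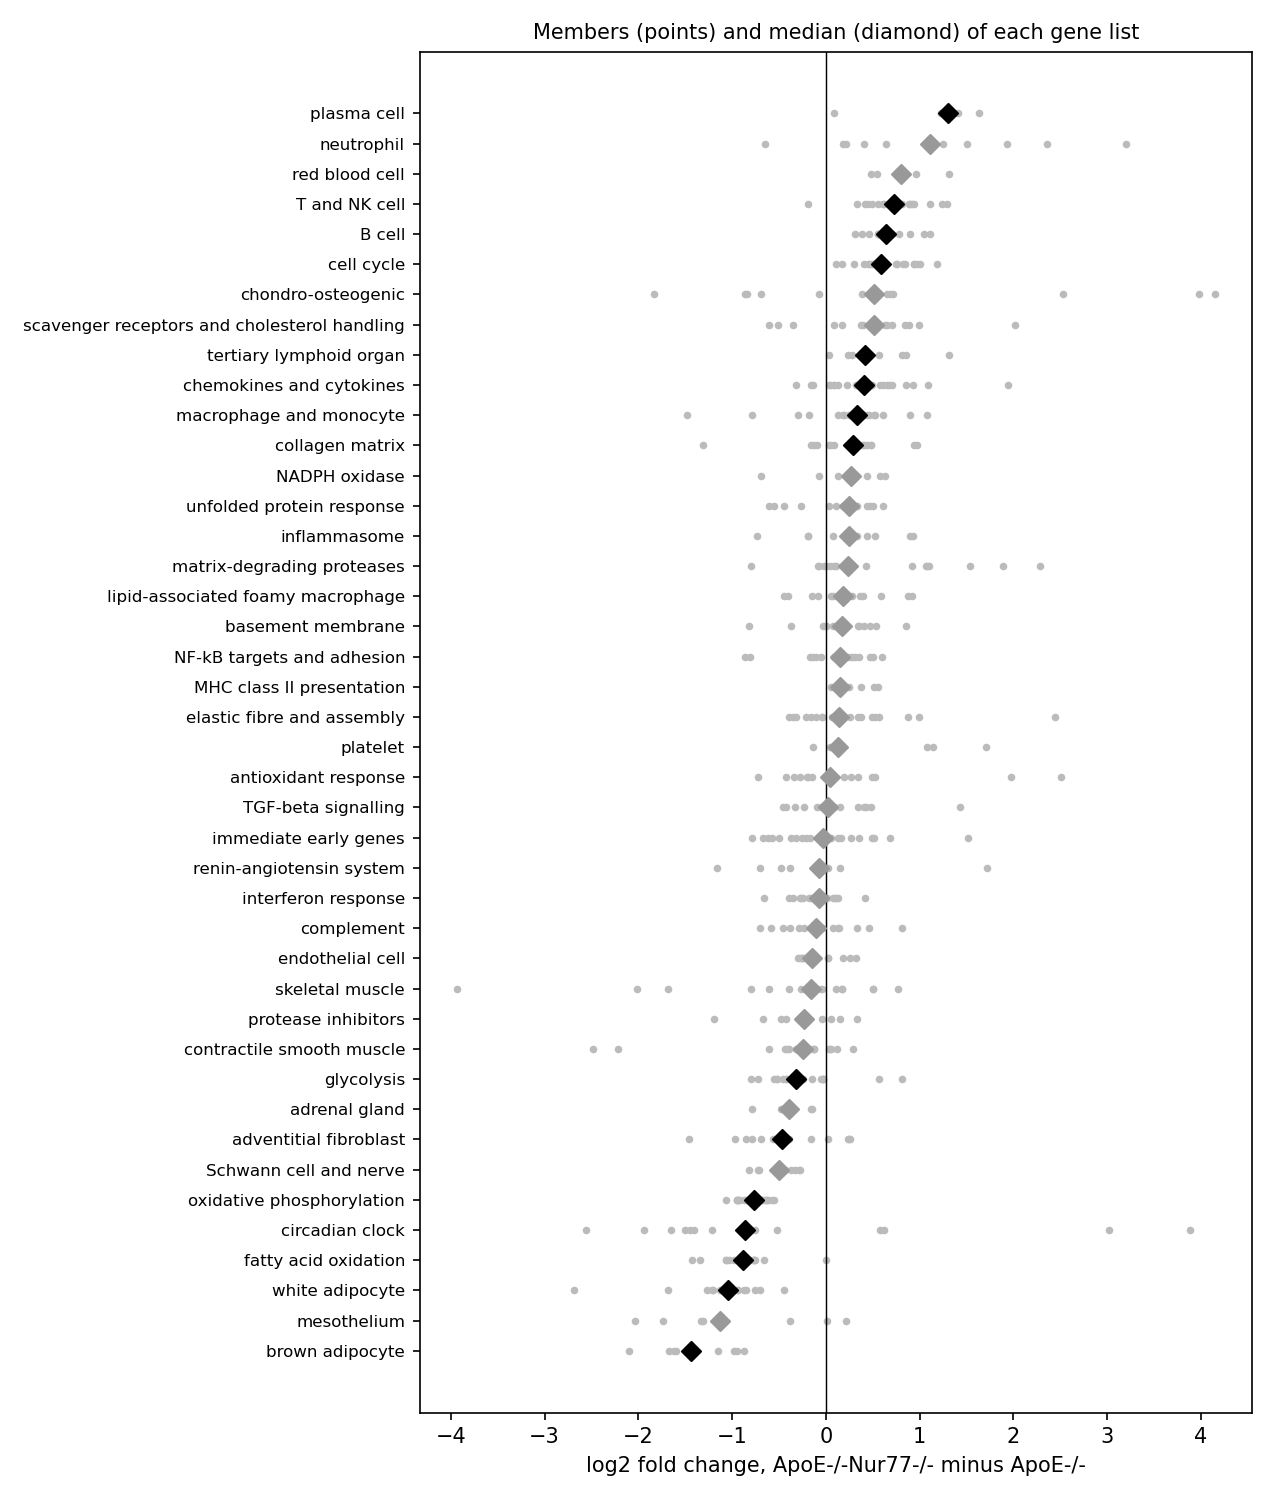
Log2 fold change (libraries labelled ApoE-/-Nur77-/- minus those labelled ApoE-/-) of each member (small points) and the median (diamond) of the 42 tested gene lists, black where camera with a preset correlation gave an adjusted p under 0.05 and grey otherwise. Brown adipocyte (-1.44) and white adipocyte genes (-1.05) lay lowest among the called lists and plasma cell genes (1.30, with 6 of 15 genes measured) highest.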

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

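Of 97 values per library tested for a single library far from the other 3 of the libraries labelled double knockout, 3 stood out, where chance gives about 1 in 20, or 4.85; groups of 3 were not tested. Cox4i1 was at 388 CPM in DKO 4 and at 296 to 299.8 CPM in the others. The mean level of elastic fibre and assembly genes was 8.42 log2 CPM in DKO 2 and 8.12 to 8.15 in the others. The mean of the 2 measured kidney genes was 1.62 log2 CPM in DKO 1 and 0.89 to 0.98 in the others.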

How the results depend on the processing

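Leaving out ApoE 3 and DKO 1 together, taking the white adipocyte level as a covariate, removing length or GC trends, and counting called lists with DESeq2, a pseudocount of 0.1 or unfiltered FPKM were chosen after seeing the data; the other alternatives were planned. Where no cause is given, the cause was not tested. Apoe was lower in all 20 alternatives (log2 fold change -3.36 to -2.72, adjusted p 1.12e-28 to 0.667) and called in 10 of them, and Nr4a1 was called in 0 (adjusted p 0.130 to 0.833). Against 4 genes lower and 0 higher, DESeq2 called 679 lower and 453 higher and limma voom 1467 and 902. FPKM called 1 gene higher with either pseudocount, Itgb3 (log2 fold change 1.14 with a pseudocount of 1), and with no filter 0 lower (Apoe -2.72). Leaving out ApoE 3 and DKO 1 together gave 2 higher, Arntl and Npas2, and 0 lower (Apoe -3.17), with fewer samples. With a GC trend removed 2 were lower, Lpin1 and Slc1a5, and Apoe was not called (-2.78, edgeR adjusted p = 0.0556). Lists called were then 12 higher and 6 lower in place of 8 and 7. Leaving out each library gave 0 to 2 genes lower and 0 to 4 higher (Akap5, Arntl, Creb3l1 and Npas2, named after their values were seen), 3 to 11 lists higher and 5 to 8 lower, and a log2 fold change of -3.07 to -2.77 for Apoe and -1.09 to -0.23 for Nr4a1. With an estimated correlation 0 lists were higher and 0 lower, and with fry 0 and 2. Lists called were 7 higher and 7 lower with DESeq2-normalised counts, 4 and 7 with a pseudocount of 0.1 (macrophage, B cell, plasma cell and tertiary lymphoid organ lost), and 8 and 7 with unfiltered FPKM. Depth limits what a count of 0 excludes to levels above 0.138 to 0.155 CPM.

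Replicate numbers 1 to 3 are shared by the groups, and the labels do not say whether they pair the samples. Deviations of same-numbered libraries correlated at -0.39, 0.70 and 0.0036, and not every library correlated best with its own number. A pairing was thus not shown and is not excluded. With the number as a block and DKO 4 left out, 0 genes were lower and 0 higher (Apoe log2 fold change -2.98), 10 lists were higher and 8 lower, and the skeletal muscle median was 0.10.

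With the white adipocyte level as a covariate 0 genes were lower, 7 lists higher and 14 lower, and Apoe was at -3.36. The covariate followed the group (Pearson r = -0.94 over 7 libraries), so standard errors grew 2.67 times at the median and the fit hardly separates the 2. In it signs turned for Nr4a1 (1.04), Olr1 (-1.94), Nr4a2 (0.089), Nr4a3 (0.29), Eng (0.20), Cd5 (-0.14), Fcrla (-3.41), Prdm1 (-0.73), Ciita (-1.22), Sod2 (0.56), Timp4 (0.92), Ace (0.60), Cybb (-1.49), Sod1 (0.31), Mki67 (-0.63), Cpt2 (0.51), Cox4i1 (0.40), Myl1 (0.28) and S100b (0.22). List medians that turned were contractile smooth muscle 1.49, endothelial cell 0.40, macrophage and monocyte -0.80, foamy macrophage -1.05, neutrophil -2.28, T and NK cell -1.50, B cell -5.10, plasma cell -1.02, tertiary lymphoid organ -2.75, MHC class II -0.20, chemokines and cytokines -0.76, NF-kB targets -0.24, inflammasome -0.26, scavenger receptors -1.05, matrix-degrading proteases -0.78, protease inhibitors 0.61, renin-angiotensin 0.30, NADPH oxidase -0.54, antioxidant response -0.23, chondro-osteogenic -0.26, immediate early genes 0.29, cell cycle -0.32, glycolysis 0.18, fatty acid oxidation 0.70, oxidative phosphorylation 0.71, white adipocyte 0.029 (set by the covariate), brown adipocyte 1.03, skeletal muscle 1.97 and platelet -0.0083.

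Outside that fit, 0 named genes and 40 of the list medians' alternative values turned sign, while 647 list values and 826 gene values kept direction and side of the threshold. Without ApoE 3 and DKO 1 together the medians that turned were foamy macrophage -0.057, neutrophil -0.25, MHC class II -0.029, chondro-osteogenic -0.078 and skeletal muscle 0.26. With voom they were interferon response 0.11 and skeletal muscle 0.43. With FPKM and a pseudocount of 1 they were complement 0.027, antioxidant response -0.020 and chondro-osteogenic -0.041; with 0.1, complement 0.027, antioxidant response -0.017 and chondro-osteogenic -0.10; with no filter, complement 0.027. Immediate early genes were at 0.00025 with RLE, 0.00046 with DESeq2, 0.061 with a length trend removed and 0.061 with a GC trend removed, where skeletal muscle was at 0.0077 and 0.038. Leaving out each library gave medians of -0.023 to 0.36 for foamy macrophage, -0.067 to 1.23 for tertiary lymphoid organ, -0.038 to 0.32 for MHC class II, -0.20 to 0.053 for interferon response, -0.21 to 0.13 for complement, -0.40 to 0.042 for renin-angiotensin, -0.044 to 0.19 for antioxidant response, -0.39 to 0.81 for chondro-osteogenic, -0.29 to 0.14 for immediate early genes, -0.74 to 0.88 for skeletal muscle, -1.47 to 0.29 for adrenal gland and -0.78 to 0.027 for Schwann cell genes.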

Other observations

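The tests on Apoe, adipocyte ratios and clock phase, the removal of length and GC trends, and the atrial and sympathetic gene lists were chosen after results were seen; the count over other splits was planned. Libraries differed in genes of tissues other than the aorta, atrial genes being high in 2 libraries labelled ApoE-/- and sympathetic neuron genes in libraries of both groups. Of an atrial cardiomyocyte list, 8 of 9 genes were measured, and their mean level was 6.92 log2 CPM in ApoE 3 and 5.06 in ApoE 2, against -0.35 to 1.47 in the other 5 libraries (exact permutation p = 0.171 between groups). Myh6, a myosin gene of cardiac muscle, was at 481 CPM in ApoE 3, 116 in ApoE 2 and 0 to 8.19 in the others. Sympathetic neuron genes (10 of 10 measured) were at 5.24, 6.48 and 6.79 log2 CPM in ApoE 1, ApoE 2 and DKO 2 and at -2.67 in ApoE 3 (exact permutation p = 0.914), with Th, which makes the catecholamine precursor, at 222 CPM in DKO 2 and 0.11 in ApoE 3. Th and Dbh are also on the adrenal gland list, and Dbh was at 409 CPM in DKO 2 and 0.33 in ApoE 3. The first principal component (49.4% of variance) set ApoE 3 and DKO 1 apart from ApoE 2 and DKO 2.

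Only 1 of the 35 splits of the 7 libraries, the real one, gave as many as 4 genes lower. The highest other gave 3 (DKO 2, DKO 3 and DKO 4 against the rest). A share of 1 in 35 is under the planned limit of 0.05, and it is the smallest that 35 splits can give. With a margin of 1 gene, chance is not firmly excluded for that count. Leaving out ApoE 1, ApoE 3, DKO 3 or DKO 4 gave 0 genes lower, ApoE 2 or DKO 2 gave 1 and DKO 1 gave 2. For 0 genes higher with edgeR (1168 at an unadjusted p under 0.05, 453 with DESeq2 and 902 with limma voom), all 35 splits gave as many, the highest other being 0, which a count of 0 fixes in advance and which says nothing on chance. For the list counts, chance was not excluded: 16 splits gave at least 8 lists higher (the highest other gave 18) and 20 gave at least 7 lower (the highest other gave 21). At an unadjusted p under 0.05, the real split gave 2892 genes, and 2 others gave more: DKO 1, DKO 2 and DKO 3 against the rest gave 4744, and ApoE 1, ApoE 3 and DKO 4 against the rest gave 4608.

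Apoe was lower in the libraries labelled double knockout although both groups carry an ApoE-/- label. One library exchanged between the groups is argued against by a ratio of 5.30 between the lowest library labelled ApoE-/- and the highest labelled double knockout. A smaller adipocyte share is argued against as the whole cause, since Apoe lay 1.91 log2 units below the white adipocyte median (-1.91, with a standard error of 0.23 for Apoe alone; per library, Apoe minus the adipocyte mean differed by -1.89, SE 0.358), although 1 of the 17 members, Lep, came near it (log2 fold change -2.68, SE 0.78). Genes within 10 Mb of Apoe differed more often than elsewhere: 13.0045% of 223 genes had p under 0.01, a larger share than in 100% of 53 blocks of as many neighbouring genes on other chromosomes (highest 8.97%), against 7.19% of the other genes on chromosome 7 and 6.43% of 140 genes around Nr4a1. Of the 4 called genes, 2 besides Apoe lay on chromosome 7, which holds 7.74% of the tested genes. Apoe itself is left out of that count, since the chromosome was chosen for it. Of these 2, Slc1a5 lay within the 10 Mb and Slc7a10 outside it. Slc7a10, a transporter of adipocytes, had a log2 fold change of -1.29, near the white adipocyte median of -1.05. A candidate explanation is that the groups differ in the DNA around Apoe, for example in the knockout allele or its donor strain. Whether it also covers Slc1a5 or Slc7a10 was not tested. A wrong genotype label and an effect of Nur77 on Apoe stay open and were not tested, since genotypes cannot be read from gene counts.

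Adipocyte and oxidative genes were lower together. Across genes the log2 fold change correlated with gene length (Spearman 0.25) and with GC content (-0.29). Each of the 2, taken alone, is argued against as the whole cause. With a length trend removed the medians were -0.62 for oxidative phosphorylation (80.3% of -0.77), -1.0018 for white adipocyte, -0.76 for fatty acid oxidation and -1.23 for brown adipocyte genes. With a GC trend removed they were -0.76, -0.99, -0.86 and -1.34. The trends were not removed together. The ratio of each of the 17 white adipocyte genes to the mean of the other members differed at adjusted p under 0.05 in 0% of them (limma on 7 libraries), but Lep (-0.89), Nnat (-0.82) and Lpl (0.67) had large shifts, and only 8 of 17 had a 95% interval within 0.5 times the list's median, so the test does not show that the ratios were kept. Cardiac muscle, rich in mitochondria, was not tested as a source of the oxidative genes: atrial genes were highest in ApoE 3 and ApoE 2, while the oxidative phosphorylation level was 7.50 in ApoE 1 (atrial level 0.13) and 7.15 in ApoE 2 (atrial level 5.06), against 6.62 to 7.13 in the libraries labelled double knockout. The brown adipocyte level ranked the libraries in the same order as the oxidative phosphorylation and fatty acid oxidation levels, from ApoE 3 (6.71 log2 CPM) to DKO 3 (4.12). That list holds Cpt1b, also a fatty acid oxidation member, and Ppargc1a, a coactivator of mitochondrial genes, so the shared order is partly built in. Ucp1 alone did not keep the order, at 256 CPM in DKO 1 and 242 CPM in ApoE 2. Brown fat was not tested as a source of the oxidative genes either. Fewer white or brown adipocytes in the libraries, a change within adipocytes, cardiac muscle and the Nur77 genotype itself stay open.

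Clock genes of opposite phase differed in opposite directions. The level of 4 Arntl-phase genes minus that of 10 Dbp-phase genes was 3.37 log2 units higher in the libraries labelled double knockout (SE 1.04, exact permutation p = 0.0571), ranging from -3.81 to -3.04 in the libraries labelled ApoE-/-, at -2.68 in DKO 1 and from 0.12 to 1.02 in DKO 2, DKO 3 and DKO 4. The ranges of the groups did not overlap, though DKO 1 lay nearer the other group than its own. This restates the observation that prompted it, and the labels give no time of collection, so a different time of day for DKO 2, DKO 3 and DKO 4 and an effect of the Nur77 genotype on the clock cannot be told apart.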
